A study of Homo sapiens with 4 samples.

How the data were processed

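RNA-seq was measured in 4 libraries of PC3 cells, an established human prostate cancer cell line, 2 transfected with siRNA against NEAT1 (siNEAT1) and 2 with a control siRNA (siNC). RNA was isolated with Trizol and libraries were made with a directional kit, per the labels' protocols. The protocol calls the siRNA siNEAT1_2, and whether this means a second siRNA sequence or one against the long isoform is not given in the sources used here. STAR, HTSeq and the genome build GRCh38 are named per the submitters' processing notes, without versions. The gene annotation release and the strand setting of the counting are not given in the sources used here, so reads of antisense neighbours and of near-identical copies, such as histone genes, may be assigned uncertainly. The deposited values are raw counts per gene, whole numbers without normalization, in 1 file per library with 60008 features. None was a summary of unassigned reads, and the 49 features of pseudoautosomal copies held a total count of 0. Groups and replicate numbers came from the sample titles. No label says whether replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

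Symbols, coordinates and gene types came from gene name tables and from GENCODE 29 on GRCh38. Of the feature identifiers, 56458 were found in GENCODE 29, 51602 of them with the same version, and 40676 in the gene name table. Library totals were 10486342 and 4419839 counts for siNEAT1 replicates 1 and 2, and 4093479 and 12941033 for siNC replicates 1 and 2. A count of 0 allows up to 0.286, 0.679, 0.733 and 0.232 CPM in these libraries, from 3 counts of the total and for counting error only. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes was 12.86 within siNEAT1 and 24.01 within siNC.

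The comparison was siNEAT1 over siNC with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM, and tested by the two-sided quasi-likelihood F test of edgeR 4 (legacy=FALSE, which is not the default of that version), with group as the only term and Benjamini-Hochberg adjusted p under 0.05. The standard error was taken as the log2 fold change over the square root of F. CPM values are counts divided by the TMM-scaled library total, on the usual scale of edgeR, and log2 CPM used a prior count of 2. Simulated data with known changes held 14145 genes. The test recovered 20 of 94 genes changed 2-fold (21.3%) and 72 of 92 changed 4-fold (78.3%), with 9 false calls. Most 2-fold changes were therefore not detectable by this fit, with group as the only term, at this depth and number of libraries. In this 1 simulated set the 9 false calls were a larger share of all calls than the threshold of 0.05 allows on average. In a simulation of 30 lists with 40 members each, 1 list shifted by 0.6 on the log2 scale had a camera adjusted p = 1.81e-12, and 0 other lists passed. Genes were drawn independently there, so it does not show how often camera errs for lists of correlated genes. In the data the estimated correlation reached 0.40 for ribosomal proteins and 0.90 for NF-kB genes.

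Gene lists were fixed before the data were examined: 37 lists, 34 of them with at least 5 tested members. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. Of the 34 lists 8 passed camera at the preset correlation and 2 passed fry. At an estimated correlation camera uses the residual degrees of freedom, 2 here, and 0 of the 34 lists passed. A large p in that setting can therefore come from few libraries as well as from correlated members. Named genes followed a rule fixed at the same time: NEAT1, CDC5L, AGRN and MALAT1; the 12 largest rises and 12 largest falls past the threshold with an average log2 CPM of at least 2, a symbol and no pseudogene type; and up to 4 members with the smallest p from each list described. The text does not name every gene that this rule takes, and counts include those left out.

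The alternatives set in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood method, no filter, a mean CPM of at least 1, a replicate block, leaving out each library, and protein-coding genes only. Leaving out a library leaves 1 in its group, and the fit then assumes that it varies like the 2 of the other group, which alone give the spread. The reduced group then holds only a deeper or only a shallower library, so differences between these also enter the fold change. A pairing of libraries by depth and a test without genes that hold a 3' UTR heptamer were added after seeing the data. Fold changes were also computed within the 2 deeper and within the 2 shallower libraries. For the scan of all heptamers, the longest annotated 3' UTR of each of 12343 protein-coding genes, of at least 50 bases, was searched, and log2 fold changes were corrected for UTR length and base composition. On shuffled fold changes with a planted heptamer, the scan ranked that heptamer lowest. Scans used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.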

Results

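Gene expression was measured by RNA-seq in PC3 cells, an androgen-independent prostate cancer line, after transfection with siRNA against NEAT1, the long noncoding RNA on which paraspeckles are built, or with a control siRNA. Each group held 2 libraries. Total counts were 10486342 and 4419839 in siNEAT1 replicates 1 and 2, and 4093479 and 12941033 in siNC replicates 1 and 2, so each group had 1 deeper and 1 shallower library. The first principal component of log2 CPM held 56.2% of the variance and separated the deeper from the shallower libraries, and the second held 34.0% and separated the groups. Values within the 2 deeper and within the 2 shallower libraries are therefore given beside the pooled ones.

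The first question was how far NEAT1 differed between the groups. NEAT1 (ENSG00000245532.5, a noncoding gene on the plus strand of chromosome 11, 65422774 to 65445540, GRCh38) measured 96.2 and 52.0 CPM in siNEAT1 replicates 1 and 2, against 198 and 792 CPM in siNC replicates 1 and 2. The means were 74.1 ± 31.3 CPM and 495 ± 420 CPM (SD, n = 2). The log2 fold change of siNEAT1 over siNC was -2.73 with SE 0.63, and it was -3.04 in the deeper and -1.92 in the shallower pair. It did not pass the test across all genes (edgeR adjusted p = 0.113). The counts are per gene and do not separate the short from the long isoform of NEAT1. The call changed when single libraries were left out: without siNEAT1 replicate 1, siNEAT1 replicate 2 or siNC replicate 1 NEAT1 passed, at -3.26, -2.36 and -3.40, and without siNC replicate 2 it did not, at -1.39. Each of these fits, here and below, leaves 1 library in a group and assumes that it varies like the 2 of the other group, so such a call does not show that a difference repeats. The library left is a deeper or a shallower one, so differences between these also enter the fold change. NEAT1 also passed without the filter on low counts, at -2.69.

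AGRN and CDC5L were measured as the other genes the study is about. AGRN, which encodes the heparan sulfate proteoglycan agrin (ENSG00000188157.13, chromosome 1, 1020123 to 1056118, plus strand), measured 453 ± 78.7 CPM in siNEAT1 and 973 ± 77.1 CPM in siNC (SD, n = 2). Its log2 fold change was -1.10 with SE 0.21, and -0.85 and -1.37 in the deeper and the shallower pair (edgeR adjusted p = 0.0756). CDC5L, a pre-mRNA splicing factor (ENSG00000096401.7, chromosome 6, 44387525 to 44450426, plus strand), measured 90.9 ± 0.296 and 102 ± 4.30 CPM. Its log2 fold change was -0.16 with SE 0.19, and -0.20 and -0.12 within the pairs (edgeR adjusted p = 0.728). MALAT1, the noncoding gene next to NEAT1, measured 1003 ± 398 and 1218 ± 989 CPM, a log2 fold change of -0.28 with SE 0.56 (edgeR adjusted p = 0.860), -0.58 in the deeper and 0.48 in the shallower pair. Of these 4 genes 0 passed over all genes with edgeR (2 at an unadjusted p under 0.05), and NEAT1 and AGRN were lower when adjusted over the list alone. AGRN passed without siNC replicate 1, at -1.01 (edgeR adjusted p = 0.0257), among protein-coding genes only (edgeR adjusted p = 0.0432), without the filter (edgeR adjusted p = 0.0134) and with DESeq2 (adjusted p = 5.98e-04). MALAT1 had a positive log2 fold change without siNEAT1 replicate 2, at 0.08, and without siNC replicate 2, at 0.97.

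**Figure D1:**
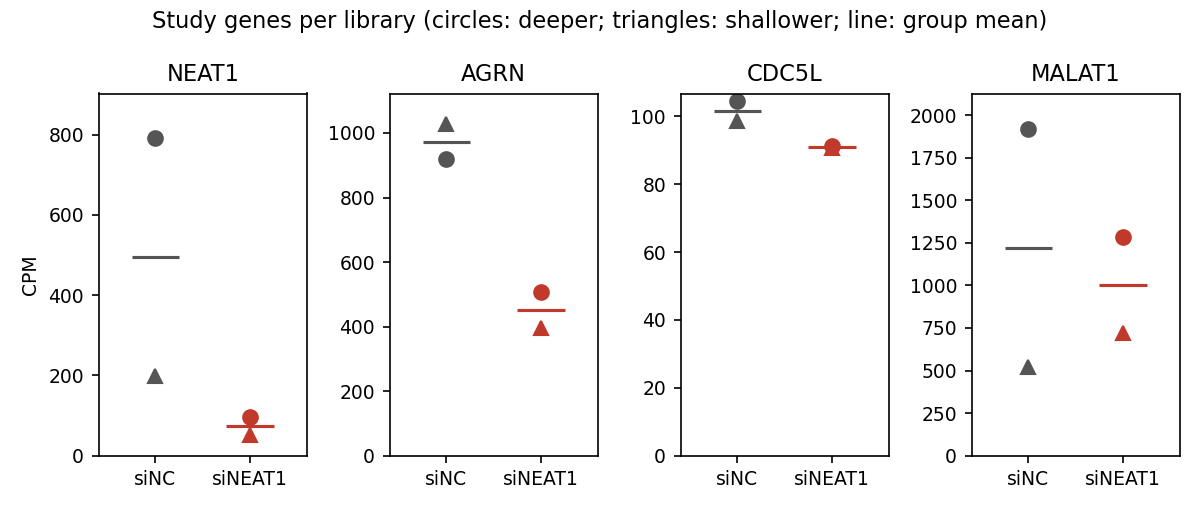
CPM of NEAT1, AGRN, CDC5L and MALAT1 in each library by group, with circles for the deeper and triangles for the shallower libraries, a horizontal line at the mean of 2 libraries, and a separate axis from 0 for each gene. NEAT1 lies at 96.2 and 52.0 CPM in siNEAT1 against 198 and 792 CPM in siNC.

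The second question was which other genes differed. UHMK1, a serine/threonine kinase that phosphorylates splicing factors, fell from 770 ± 285 to 49.8 ± 0.552 CPM (SD, n = 2), a log2 fold change of -3.95 with SE 0.31 (edgeR adjusted p = 0.0168). The histone gene H3C13 fell from 240 ± 4.17 to 29.6 ± 0.476 CPM, a log2 fold change of -3.02 with SE 0.20. Lower too were PAPSS2, which makes the sulfate donor of the cell, at -2.93, TMEM64 at -2.80, ERI1, an exonuclease that acts on histone mRNA, at -2.68, and API5, an inhibitor of apoptosis, at -2.65. The other named falls were BRI3BP at -2.56, LRRC58 at -2.55, the G protein subunit GNAI3 at -2.48, CEP55, which acts in cytokinesis, at -2.44, TOR1B at -2.40 and the nucleotide kinase CMPK1 at -2.39. FSIP2 rose from 6.29 ± 0.927 to 36.6 ± 8.13 CPM, a log2 fold change of 2.49 with SE 0.29 (edgeR adjusted p = 0.0346), and FKBP14, a prolyl isomerase of the endoplasmic reticulum, rose from 30.5 ± 2.56 to 152 ± 17.3 CPM, by 2.31 with SE 0.21. ZNF616 rose by 2.20, the tropomyosin TPM4 by 2.14, DISP2 by 2.14, MDGA2 by 2.08 and the phospholipase PLA2G4A by 2.03. The methyltransferase SETD7 rose by 1.95, GLIPR1 by 1.86, ZNF724 by 1.76 and BTN3A2 by 1.73. The heptamer AATCTTA or ATCTTAA stood in the annotated 3' UTR of each of these falls except H3C13, and among the rises in that of ZNF616, DISP2 and GLIPR1. H3C13 had no annotated 3' UTR to search, so a match in it stays open. Without siNC replicate 2, FSIP2 (2.70), ZNF616 (1.93), DISP2 (1.92), MDGA2 (2.31), PLA2G4A (2.05), ZNF724 (1.97) and ERI1 (-2.50) missed the threshold. SETD7 missed it with RLE (1.95), upper-quartile scaling (1.99) and the legacy method (1.94), and MDGA2 with limma-voom (2.05) and the legacy method (2.10).

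Of 14729 genes tested 92 passed (edgeR, 2 libraries per group), 18 higher and 74 lower. Each was changed at least 2-fold and in the same direction in both pairs. The groups did not overlap in any of the 92, which by itself fixes that direction, so it is no separate check. At an unadjusted p under 0.05 there were 1118 higher and 1291 lower genes. The count depended on single libraries: it was 265 without siNEAT1 replicate 1, 303 without siNEAT1 replicate 2, 611 without siNC replicate 1 and 74 without siNC replicate 2. DESeq2 called 590 genes, 214 higher and 376 lower, and edgeR called 249 without the filter and 263 among protein-coding genes only. Counts of list members past the threshold over all genes are by edgeR, and limma-voom called 0 members of each list in which edgeR called 0, except 1 gene of G2 and mitosis.

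**Figure D2:**
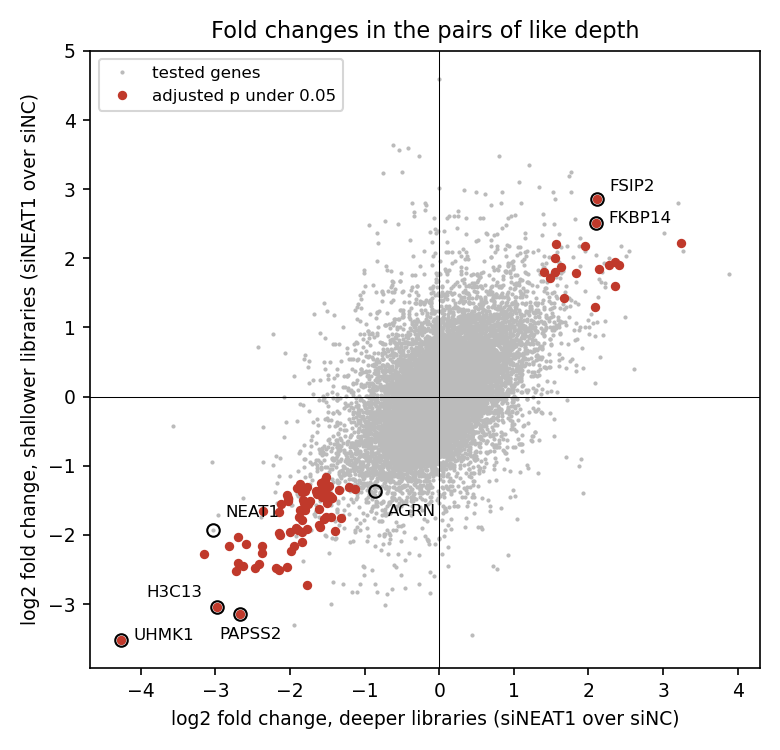
Log2 fold change (siNEAT1 over siNC) of 14729 tested genes, in the 2 deeper libraries on the horizontal and in the 2 shallower libraries on the vertical axis, with the 92 genes past the threshold in red and named genes ringed. UHMK1 lies at -4.27 and -3.52, and NEAT1, which did not pass, at -3.04 and -1.92.

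Replication-dependent histone genes, which supply histones in S phase, were lower as a group. Of 39 tested, 14 fell and 0 rose, and 37 fell when adjusted over the list alone; the same number, 37, were lower in both pairs. H2AC12 fell by 2.38, H3C3 by 2.08, H3C1 by 2.05 and H2BC13 by 1.82. The median log2 fold change was -1.21, and it was -1.32 in the deeper and -1.17 in the shallower pair. The list passed camera (adjusted p = 2.30e-25) and fry (adjusted p = 0.0341), but camera gave adjusted p = 0.381 with an estimated correlation. The number of called histone genes was 30 without siNC replicate 1, 10 without siNC replicate 2, 7 with the legacy method, 23 without the filter, 26 among protein-coding genes only and 34 with DESeq2. Reads of such near-identical copies are split among them with uncertainty.

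Genes of the G1/S transition and DNA replication were also lower. FEN1, the flap endonuclease of lagging-strand synthesis, fell by 1.64 and UHRF1, which helps to maintain DNA methylation, by 1.26, the only 2 of 48 members past the threshold over all genes, while 24 fell when adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, was at -1.26 and the checkpoint mediator CLSPN at -1.17. The median was -0.63 in the pooled comparison and in each pair, with 39 members lower in both pairs. The list passed camera (adjusted p = 1.46e-11) and fry (adjusted p = 0.0341), but camera gave adjusted p = 0.381 with an estimated correlation. Its estimated correlation was -0.00868, below the preset 0.01, so correlated members do not explain the larger p there. Called members were 12 without siNC replicate 1, RRM2 (-1.44) and CLSPN (-1.14) among them, 1 without siNC replicate 2, 1 with the legacy method, 5 without the filter, 8 among protein-coding genes only and 15 with DESeq2. FEN1 missed the threshold without siNC replicate 2 (-1.54) and UHRF1 without that library (-1.21), without siNEAT1 replicate 2 (-1.18) or with the legacy method (-1.26).

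Other lists of the cell cycle did not pass camera. Of 62 genes of G2 and mitosis 0 passed over all genes and 2 fell when adjusted over the list alone, the topoisomerase TOP2A at -1.24 and ANLN at -1.06, beside ECT2 at -0.74 and UBE2C at -0.66 (median -0.10, camera adjusted p = 0.187). Of 47 DNA repair genes 0 passed over all genes and 2 fell over the list alone, RNF168 at -1.25 and H2AX at -1.11, beside EXO1 at -0.69 (median -0.16, camera adjusted p = 0.267). Of 11 inhibitors of cyclin-dependent kinases 0 passed over all genes and CDKN2B, at 0.98, over the list alone, beside CDKN2C at -1.19, RB1 at 0.54 and CDKN1A at -1.07 (median -0.17, camera adjusted p = 0.888). Of 27 p53 targets 0 passed over all genes and 3 fell over the list alone, CCNG1 at -1.33, RRM2B at -1.11 and TP53INP1 at -2.49, beside SESN2 at 0.88 (median -0.13, camera adjusted p = 0.243). Without siNC replicate 1, TOP2A (-1.36), ANLN (-0.95), RNF168 (-1.22) and H2AX (-1.06) passed over all genes, and these lists had 5, 4, 1 and 3 called members in the order above. Without siNEAT1 replicate 1 or 2, 1 and 1 of the kinase inhibitors and 2 and 1 of the p53 targets passed. In the order of the 4 lists, 12, 9, 2 and 5 members had an unadjusted p under 0.05 with edgeR, DESeq2 called 2, 2, 1 and 3, edgeR without the filter 2, 0, 0 and 2, and edgeR among protein-coding genes only 2, 2, 0 and 0.

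**Figure D3:**
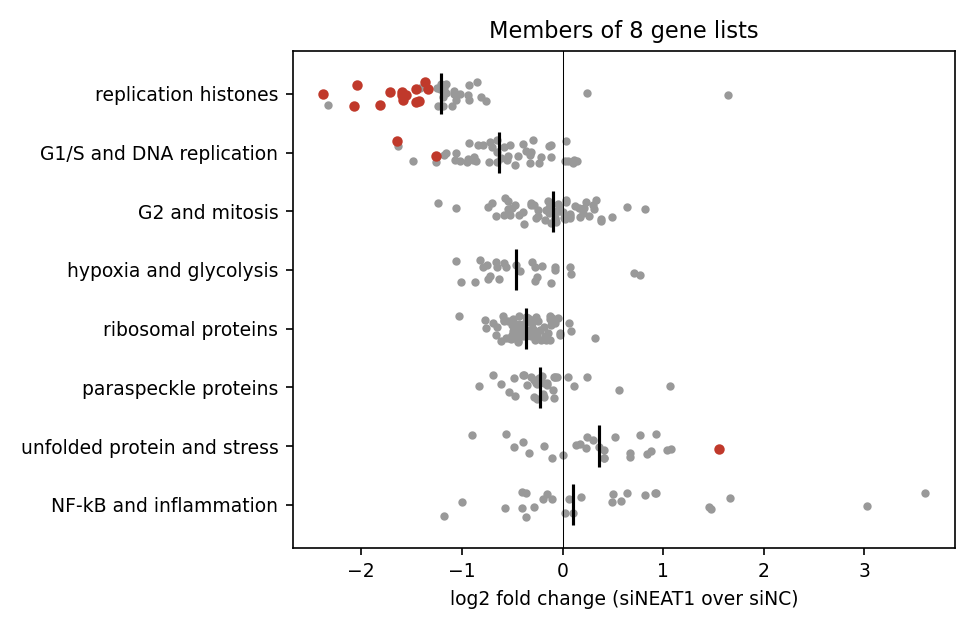
Log2 fold change (siNEAT1 over siNC, horizontal axis) of each tested member of 8 gene lists, with members past the threshold over all genes in red, the others in grey and a vertical line at each list's median. The medians lie at -1.21 for replication histones, -0.63 for G1/S and DNA replication and 0.36 for the unfolded protein and stress list.

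Hypoxia and glycolysis genes were lower as a list by camera at the preset correlation. Neither they nor the lists of ribosomal proteins and of ribosome biogenesis below passed fry (adjusted p = 0.476 for each). The glycolytic enzymes LDHA, TPI1 and GPI were at -1.06, -0.79 and -0.75 and the mitophagy receptor BNIP3 at -1.01; 0 of 27 members passed over all genes and 8 fell when adjusted over the list alone. The median was -0.46, with -0.49 in the deeper and -0.57 in the shallower pair (camera adjusted p = 2.60e-04, and adjusted p = 0.986 with an estimated correlation). Of 74 ribosomal protein genes 71 had a negative log2 fold change, 0 passed over all genes or over the list alone, and the median was -0.36, with -0.17 and -0.55 within the pairs. RPS16 was at -1.03, RPL32 at -0.76, RPL8 at -0.69 and RPL15 at -0.61 (camera adjusted p = 1.35e-07, and adjusted p = 0.986 with an estimated correlation). The 25 genes of ribosome biogenesis and MYC had 0 members past either threshold and a median of -0.29, with BOP1 at -0.74, NOP56 at -0.60, NCL at -0.56 and NOP2 at -0.49 (camera adjusted p = 0.0472, and adjusted p = 0.986 with an estimated correlation). Without siNC replicate 1, LDHA (-1.05) and BNIP3 (-1.04) passed over all genes, with 1 further gene of their list that was higher, and so did 1 ribosomal protein gene. For the 3 lists in this order, 13, 12 and 4 members had an unadjusted p under 0.05 with edgeR, DESeq2 called 7, 2 and 0, all lower, edgeR without the filter 2, 0 and 0, and edgeR among protein-coding genes only 2, 1 and 0.

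Genes of the unfolded protein and integrated stress responses were higher as a list by camera at the preset correlation. Neither this list nor the fibroblast markers below passed fry (adjusted p = 0.476 for each). The cystine transporter SLC7A11 rose by 1.55, the only 1 of 27 members past the threshold over all genes, and 5 rose when adjusted over the list alone. HERPUD1, which acts in the degradation of misfolded proteins, was at 1.07, the phosphatase subunit PPP1R15A at 0.93 and the cochaperone DNAJC3 at 0.84. The median was 0.36, with 0.46 in the deeper and 0.17 in the shallower pair (camera adjusted p = 0.0174, and adjusted p = 0.986 with an estimated correlation). SLC7A11 missed the threshold without siNC replicate 2 (1.41), and HERPUD1 (1.02) and PPP1R15A (1.08) passed without siNC replicate 1, which gave 3 called members; DESeq2 called 4, all higher, and edgeR among protein-coding genes only 2. Of 5 tested fibroblast markers 0 passed over all genes and 3 were higher over the list alone, PDGFRA at 1.58, COL3A1 at 1.10 and COL1A1 at 0.66, beside ACTA2 at 1.26 (median 1.10, camera adjusted p = 0.0202, and adjusted p = 0.986 with an estimated correlation). PDGFRA and COL1A1 measured 9.05 and 84.7 CPM in siNEAT1 and 2.71 and 53.1 CPM in siNC; 3 markers had an unadjusted p under 0.05 with edgeR, and DESeq2 called 0. Of the blood and endothelial markers 1 could be tested, PECAM1 at -0.02, 0.02 with upper-quartile scaling and 0.04 without the filter.

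Genes near NEAT1 on chromosome 11 and genes of its protein partners were compared as well. The neighbours did not pass fry (adjusted p = 0.476). The 16 tested neighbours had 0 members past either threshold and a median of -0.32, with -0.22 and -0.45 within the pairs, FRMD8 at -0.78, LTBP3 at -0.72, RELA at -0.50 and MAP3K11 at -0.46 (camera adjusted p = 0.0321, and adjusted p = 0.986 with an estimated correlation). The 32 genes of paraspeckle proteins had 0 members past either threshold and a median of -0.22, with FAM98A at 0.56 and RBM14 at -0.69 (camera adjusted p = 0.0880). The 17 genes of the CDC5L complex had 0 past either threshold and a median of 0.07, with XAB2 at -0.82 and PLRG1 at 0.51 (camera adjusted p = 0.970). The 24 tested nuclear noncoding RNAs and host genes of small nucleolar RNAs had 0 past either threshold and a median of -0.26, with CYTOR at -0.77 (camera adjusted p = 0.187). The 12 genes of microRNA maturation had 0 past either threshold and a median of -0.12, with DICER1 at -1.39 (camera adjusted p = 0.624); DICER1 passed without siNEAT1 replicate 1, at -1.66, and without siNC replicate 1, at -1.93, where AGO2 passed too, at -0.93. At an unadjusted p under 0.05 these 5 lists had, in order, 3, 4, 2, 1 and 2 members with edgeR, and DESeq2 called 0 in each.

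Genes of cell death, adhesion and interferon response moved in both directions. Among 24 apoptosis genes 1 higher and 1 lower passed over all genes, the latter MCL1, a survival factor of the BCL2 family, which fell by 1.70, and 1 higher and 4 lower genes passed over the list alone, PMAIP1 at -0.99 and APAF1 at -1.26 among them (median -0.42, camera adjusted p = 0.138). Among 40 interferon-stimulated genes OASL fell by 2.33, a call lost with upper-quartile scaling (-2.29), limma-voom (-2.26) and the legacy method (-2.33), and 2 higher and 3 lower genes passed over the list alone, with ISG15 at -1.19, IFI44L at 1.78 and SAMD9L at 1.47 (median 0.08, camera adjusted p = 0.672). Among 35 basement membrane genes the laminin receptor subunit ITGA6 fell by 1.39, a call lost without siNEAT1 replicate 1 (-1.35), and 4 higher and 3 lower genes passed over the list alone, with LAMA5 at -1.37 and ITGB1 at 0.79. The median of that list was -0.01, 0.03 with upper-quartile scaling and 0.08 without the filter (camera adjusted p = 0.985). Of 27 mesenchymal genes 0 passed over all genes and 3 were higher and 4 lower over the list alone, with FBN1 at 1.14, VIM at -0.94, CDH11 at -0.86 and CDH2 at -0.87 (median 0.10, camera adjusted p = 0.753). Epithelial genes (22 tested, median -0.10, ITGB4 at -1.28, camera adjusted p = 0.688) and YAP targets (18 tested, median 0.01, AXL at -0.68, camera adjusted p = 0.983) had 0 members past either threshold. Of 13 Wnt targets 0 passed over all genes and DKK1, at -1.01, over the list alone (median 0.03, camera adjusted p = 0.983). Without siNEAT1 replicates 1 and 2 and siNC replicates 1 and 2, in this order, called members were 5, 2, 5 and 1 for apoptosis, 3, 3, 4 and 3 for interferon response, 0, 4, 3 and 1 for basement membrane and 1, 1, 3 and 0 for mesenchymal genes. In the same order they were 2, 2, 0 and 0 for epithelial genes, 0, 1, 1 and 0 for YAP targets and 0, 0, 1 and 0 for Wnt targets. DESeq2 called 5 apoptosis, 4 interferon, 7 basement membrane and 6 mesenchymal genes (2 higher and 4 lower), 1 epithelial gene, 2 YAP targets and 1 Wnt target. Without the filter edgeR called 4 interferon, 4 basement membrane, 2 mesenchymal and 1 Wnt gene, and among protein-coding genes only 3, 3, 1 and 0. Mesenchymal, epithelial, YAP and Wnt genes with an unadjusted p under 0.05 were 8, 5, 3 and 2.

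The NF-kB genes differed between the deeper and the shallower libraries. CXCL8, a chemokine chosen after its values were seen, measured 3113 and 1119 CPM in the deeper and 44.5 and 28.9 CPM in the shallower library of siNEAT1 and siNC. Of 27 NF-kB genes 23 were higher in both deeper than in both shallower libraries, and between the groups 0 passed over all genes or over the list alone (median 0.10, with 0.18 and -0.14 within the pairs, camera adjusted p = 0.983). That count of 0 depended on single libraries: without siNEAT1 replicate 1 there were 16 called members, all lower, and without siNEAT1 replicate 2 there were 12, all higher. In those fits the lone siNEAT1 library is assumed to vary like the 2 of siNC, and the direction depends on which library is left, so these calls cannot be read as group differences. Without the filter 1 was called, 1 had an unadjusted p under 0.05 with edgeR, and DESeq2 called 0. PTGS2 was at 3.60 and IL6 at 3.02; both passed without siNEAT1 replicate 2, at 4.45 and 4.05, and IL6 was at -1.57 without siNEAT1 replicate 1. Of 19 immediate early genes 0 passed either threshold, with SPRY2 at 0.93 (median -0.27, camera adjusted p = 0.570), and 1 passed without siNEAT1 replicate 2 and 1 with DESeq2, while 2 had an unadjusted p under 0.05 with edgeR.

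**Figure D4:**
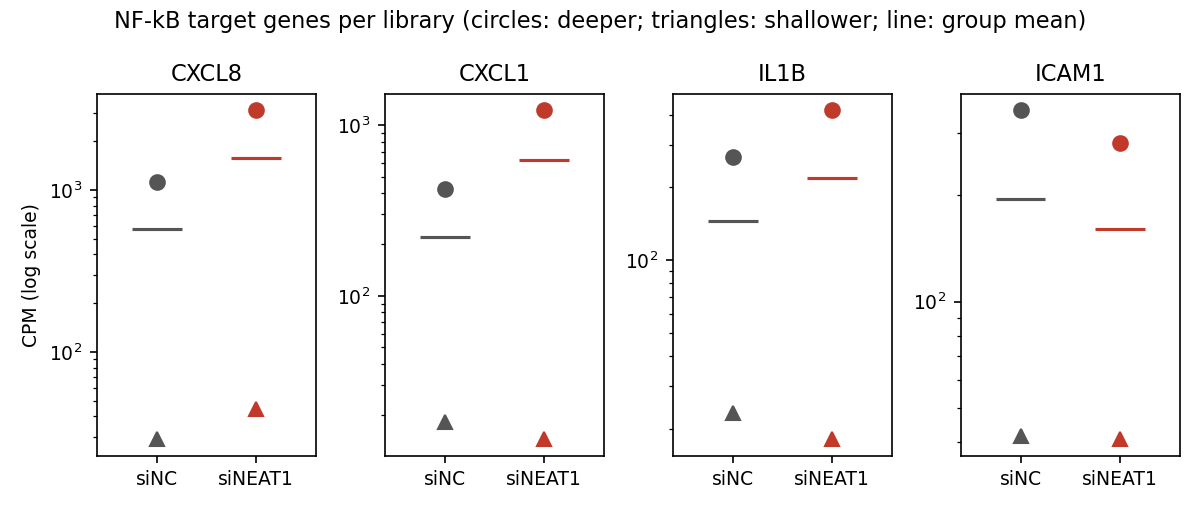
CPM (log axis, separate for each gene) of CXCL8, CXCL1, IL1B and ICAM1, chosen after their values were seen, in each library by group, with circles for the deeper and triangles for the shallower libraries and a horizontal line at the mean of 2 libraries. CXCL8 lies at 3113 and 1119 CPM in the deeper and at 44.5 and 28.9 CPM in the shallower libraries.

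The remaining lists of metabolism and protein quality control, and those of prostate cell identity, did not pass camera or could not be tested. Of 42 oxidative phosphorylation genes 0 passed either threshold, with SDHA at -0.77 and NDUFV1 at -0.70 (median -0.22, camera adjusted p = 0.0594). The 12 mitochondrially encoded genes had 0 past either threshold and a median of -0.12 (camera adjusted p = 0.517); MT-ND2 was at 0.81, passed without siNEAT1 replicate 1 at 1.44 and was at -0.24 without siNEAT1 replicate 2. The 22 cholesterol synthesis genes had 0 past either threshold, with SC5D at -1.29 and IDI1 at -0.96 (median -0.18, camera adjusted p = 0.196). Of 12 fatty acid synthesis genes 0 passed over all genes and ME1, at 1.11, over the list alone (median 0.03, camera adjusted p = 0.983). Of 19 NRF2 targets SLC7A11 rose, and 3 higher and 1 lower passed over the list alone, with ME1, HMOX1 at 1.02 and SOD1 at -0.99 (median -0.08, camera adjusted p = 0.753). Of 17 heat shock genes 0 passed over all genes and DNAJB4, at 1.67, over the list alone (median -0.29, camera adjusted p = 0.267). Of 21 autophagy and lysosome genes 0 passed over all genes and WIPI1, at 1.32, over the list alone (median -0.03, 0.01 with upper-quartile scaling and 0.04 without the filter, camera adjusted p = 0.986). The 31 proteasome genes had 0 past either threshold, with PSMD7 at -0.78 (median -0.03, 0.01 with upper-quartile scaling and 0.07 without the filter, camera adjusted p = 0.983). Of the prostate lists, 10 androgen-response genes had 0 past either threshold, with PMEPA1 at -0.69 and HOXB13 at -0.60 (median -0.14, camera adjusted p = 0.908). Of the neuroendocrine genes 3 could be tested, SYP at 0.92, ENO2 at -0.42 and NCAM1 at -0.26, and 0 passed either threshold. Without siNC replicate 1, called members were 3 for cholesterol synthesis, 2 each for NRF2 targets and heat shock, and 1 each for oxidative phosphorylation, fatty acid synthesis and autophagy. Without siNEAT1 replicate 1 they were 2 for mitochondrially encoded and 1 for heat shock genes, and without siNC replicate 2 they were 0 for NRF2 targets. DESeq2 called 4 NRF2 targets, 2 autophagy genes, 1 gene each of oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis and heat shock, and 0 in the other lists of this group; edgeR called 1 heat shock gene without the filter and 1 among protein-coding genes only. Members with an unadjusted p under 0.05 were 8 for oxidative phosphorylation, 1 mitochondrially encoded, 3 for cholesterol and 4 for fatty acid synthesis, 2 for heat shock, 2 for autophagy, 1 for the proteasome and 0 for the prostate lists.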

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

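The pairing by depth, with and without the legacy method, and the test without genes that hold AATCTTA or ATCTTAA were chosen after seeing the data. RLE, upper-quartile scaling, limma-voom, the legacy method and a mean CPM of at least 1 gave 86, 93, 98, 62 and 92 genes past the threshold. DESeq2 gave 590 (441 at least 2-fold), no filter 249 (238 at least 2-fold), and the 4 settings that leave out 1 library from 74 to 611 (74 to 505 at least 2-fold); the cause was not tested. Protein-coding genes only gave 263 (260 at least 2-fold), over 12485 genes tested. With a replicate block 17 passed, 1 higher and 16 lower, with 2 histone and 0 G1/S genes among them, and same-numbered deviations from the group means correlated at -0.674. Pairing by depth instead, with 1 residual degree of freedom, gave 2237 genes, 1068 higher and 1169 lower (953 at least 2-fold), and 2193 (932) with the legacy method, among them 85 and 84 of the 130 other named genes, with AGRN, 11 NF-kB genes (8 higher, 3 lower) and 485 heptamer genes of 1044 searched lower ones, while the NEAT1 neighbours and ribosome biogenesis lost their camera calls. Without the genes that hold a heptamer 4 of 11942 passed; this setting only adjusts p again, and fold changes and unadjusted p stay as they were, so these lost calls do not show that a fall depends on the heptamer. The share of lower genes was 80.4%, 63.7% with DESeq2 and 59.4% without the filter, 94.1% with the replicate block and 52.3% paired by depth. NEAT1 had a negative log2 fold change in each setting, from -3.40 to -1.39 without 1 library, -2.69 without the filter and -2.51 by both methods paired by depth, and passed in the last 2 settings. Values that turned sign were PECAM1 with upper-quartile scaling (0.0235) and no filter (0.0404) and, without 1 library, MALAT1 (-0.93 to 0.97), NCAM1 (-1.10 to 0.59), IL6 (-1.57 to 7.51), MT-ND2 (-0.24 to 1.44), PECAM1 (-0.0888 to 0.116) and HOXB13 (-0.998 to 0.00404); the cause was not tested, and none had passed in the comparison of all 4 libraries. Of 34 named genes past the threshold 0 turned sign; the call was lost by 21 with the replicate block, 11 without siNC replicate 2, 4 with the legacy method and 13 of the 17 that remained without heptamer genes. Of these 130 other genes 42 passed with DESeq2, 38 without siNC replicate 1, 9 without siNEAT1 replicate 1, 9 without siNEAT1 replicate 2, 2 without siNC replicate 2, 18 without the filter and 1 with limma-voom, and 16 of 124 among protein-coding genes only. Ribosome biogenesis genes also lost their camera call with the replicate block (adjusted p = 0.0565). At 4093479 to 12941033 counts and 2 libraries per group, the fit with group alone missed most 2-fold changes in the simulation.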

Other observations

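The tests of exchanged labels, of NF-kB genes, of RNA without a poly(A) tail and of histone genes without a heptamer, and the comparison of heptamer shares, were chosen after the results were seen. Protein-coding genes with a ZNF symbol, most of which encode zinc finger proteins that bind DNA, were picked after ZNF616 and ZNF724 were seen among the calls, so these values describe the class and cannot test it. Of 402 tested 2 rose, ZNF616 and ZNF724, and 0 fell (edgeR; 56 higher and 13 lower at an unadjusted p under 0.05), DESeq2 called 16 higher and 2 lower, and 50.5% were higher in both pairs against 33.8% of all tested genes. Their median log2 fold change was 0.22, with 0.20 in the deeper and 0.27 in the shallower pair, 0.26 with upper-quartile scaling and 0.20 without genes that hold a heptamer. Thinned to 4093479 counts each, 23436 and 25270 genes had a count in the deeper libraries of siNEAT1 and siNC, and 32809 and 28868 in the shallower ones.

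Genes with the heptamer AATCTTA in their 3' UTR tended to be lower in siNEAT1. Its score over genes was the lowest of all heptamers, -27.6 (n = 12343, Bonferroni p = 5.71e-159, genes taken as independent). Within the deeper and the shallower pair it was -25.6 and -24.2. By longest match, the uncorrected median log2 fold change was -0.29 for AATCTTAA (733 genes), -0.05 for AATCTTA (1104) and 0.02 for ATCTTAA (950). It was 0.12 for ATCTTA (1338 genes) and -0.01 without a match (8218). In this order of the classes, 28, 19, 5, 4 and 10 genes were called lower. The octamer class had the lowest median, but these medians are not corrected for UTR length and base composition. UTR length and base composition explained 8.45% of the variance, 2.57% in the deeper and 17.9% in the shallower pair, which argues against them as the whole cause. The genes called lower had a median of -1.84 after the correction, against -1.77 before. They were selected for large falls in the same data, so at so small a share that median could hardly move and adds little. AATCTTA or ATCTTAA stood in 52 of 66 searched genes called lower (78.8%) and in 22.3% of the others (Fisher's exact test, two-sided, p = 4.20e-22), with heptamers picked from the same data. Of the called falls named from lists other than histones, FEN1, MCL1 and ITGA6 held a heptamer, and UHRF1 and OASL did not. Silencing of other transcripts through an siRNA seed, which would read UAAGAUU, may therefore account for some of the falls; the siRNA sequence is not given in the sources used here, nor whether the name siNEAT1_2 means a second siRNA or the long isoform, and an effect of NEAT1 loss on these genes stays open. The octamer AATCTTAA also occurs 4 times in the NEAT1 transcript of 22743 bases (0.511 by its base composition), on chromosome 11 (GRCh38) at 65424202 to 65424209, 65433431 to 65433438, 65435978 to 65435985 and 65438289 to 65438296.

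Deviations from the group means put siNEAT1 replicate 1 with siNC replicate 2, the deeper libraries. After thinning to equal totals in 20 draws, same-numbered deviations still correlated at -0.609 on average, from -0.617 to -0.600, which argues against depth as the cause. An exchange of group labels between 2 libraries is argued against by the heptamer score, -24.2 in the pair where it was nearer 0. The heptamer was picked in the pooled comparison under these labels, but it also had the lowest score within each pair. NEAT1, which was lower in the library labelled siNEAT1 in both pairs, argues against exchanged labels too. Replicate numbers exchanged within a group would leave these values as they are, so that stays open. The 27 NF-kB genes had a median log2 difference of 3.04 between deeper and shallower libraries, with CXCL1 at 1232 and 424 CPM against 14.4 and 18.2 CPM. This list was singled out because it showed the difference, so the value cannot test whether NF-kB activity differed between the cultures behind these libraries, which stays open; no label gives a batch.

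The 39 replication-dependent histone genes had a median log2 fold change of -1.21. Small RNA genes without a poly(A) tail (84 tested) had a median of -0.31, above the histones (permutation test over genes, two-sided, p = 1e-05, the smallest that 100000 resamples can give). The test takes genes as independent, which near-identical histone genes are not, and does not measure the spread between libraries. The difference in medians shows that these small RNA genes were lowered less than the histones. Their median was itself below that of all tested genes, -0.01. Reads of small RNA genes may come from host genes, so the test cannot decide on a lower yield of RNA without a poly(A) tail, which stays open. Of the 14 histone genes called lower 7 had an annotated 3' UTR to search, and 1 of these (14.3%) held a heptamer, so seed matches stay open for that gene and for the 7 called genes without an annotated 3' UTR. The 18 searched histone genes without either heptamer had a median of -1.20, with quartiles of -1.40 and -0.96, which argues against direct seed silencing for those genes. Fewer cells in S phase may lower histone mRNA, but no value here measures the share of such cells, so this was not tested. The G1/S list kept a median of -0.59 without genes that hold a heptamer. An effect of NEAT1 loss and an indirect one of the siRNA stay open, and neither was tested.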
